A study of Bacillus subtilis with 16 samples.

How the data were processed

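Total RNA of 2 strains on 4 sugars was labelled with dyes and hybridized to microarrays, 16 samples in 8 groups of 2. Groups and replicate numbers were taken from the labels. Per the labels' protocols, cells were grown in GM17 medium, RNA was purified with a commercial kit and treated with DNase, and cDNA carrying aminoallyl groups was coupled to either of 2 dyes. The scanner, the image analysis and the background settings are not given in the sources used here. The labels name the same dye for every sample. Each title holds a number and a letter. The 2 samples of a sugar that share a number were taken as the channels of 1 array, an assumption that the labels do not state. Deviations of such pairs correlated at a median of 0.484 over 8 pairs, from 0.0286 to 0.777, and those of the 2 samples of a group at a median of 0.294, from -0.0111 to 0.508. On mannitol the order was the other way, with 0.218 and 0.0286 for the presumed arrays and 0.508 and 0.298 for the groups. A samples were brighter than B samples throughout. The loess step and the array block rest on this assumption, and quantile normalization, an alternative, does not. KMO and KM283 each held both letters on every sugar, so a dye effect cancels in a strain comparison.

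The deposited intensity values came as 3 tables. The first holds 1 spot per gene, 4173 rows, as linear intensity with a gene name and a protein accession, and was used for all main results. The second, the deposited series matrix, holds 15744 spots in linear intensity, filled in 15 of 16 samples (KMO maltose replicate 1 is empty), and each of the 4173 rows matched exactly 1 of its spots. The third holds intensity per locus tag which, per the labels' design text, the authors combined over probes and normalized by TMM, in the same 15 samples.

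The design fixed before the data were examined named the TMM table as the main values. It was replaced because its locus tags did not match the other tables. By locus, its Spearman correlation with the spot table across genes lay between -0.0138 and 0.00786 in every sample. Sample profiles of neighbouring loci had a median correlation of -0.000797 in the TMM table and 0.193 in the spot table, where 100 shuffled orders gave at most 0.022. The median level of 56 ribosomal protein genes lay at percentile 47 in the TMM table and 99 in the spot table. The test, samples and covariates of the design were kept.

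Of 4173 genes 4157 were named through their protein accession in the reference table of assembly ASM904v1, and 16 keep the name in the file. Current symbols in that table are lctE for ldh and ywpJ for phoC. Intensities were floored at 0 (1 value in each of 3 samples was 0 or below), 1 was added and log2 taken. The log ratio of the 2 channels was normalized by loess within each array and mean intensities by Aquantile between arrays, and 1 log2 value per sample was recovered. A fold change is on the log2(value + 1) scale. Values above 60000, near the top of the range, occurred for 5 to 45 genes in each A sample and for 0 genes in B samples. Among named genes these include manP, yjdF, ptsG, mtlF, mtlA, pyrAB, pyrE, pyrF, lctE, gapA and pdhB, whose differences may be understated.

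limma 3.58.1 in R 4.3.3 fitted 1 coefficient per group over 16 samples (lmFit, eBayes, 8 residual degrees of freedom, 3.47 prior degrees of freedom) with no covariates. Benjamini-Hochberg adjustment ran over 4173 genes and calls were made at an adjusted p under 0.05. There were 13 comparisons: 4 between strains, 6 of a sugar with glucose within a strain, and 3 of strain differences. Lists of genes, 37 fixed before the data were examined, were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry, adjusted over the lists within a comparison. Of the camera calls on mannose between strains, 6 of 18 held with an estimated correlation. Over the 4 strain comparisons 14, 15, 13 and 18 lists were called and 0, 3, 6 and 6 held on glucose, maltose, mannitol and mannose.

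Named genes followed a rule fixed beforehand. For the strains on mannose it took up to 12 called genes in each direction with the largest change and replicates that did not overlap, and for each other comparison up to 5. It added the members of the lists for the glcR-phoC operon, mannose utilisation and mannose-6-phosphate isomerases whether called or not. For other lists described it took up to 4 called members, or the 2 largest changes where none was called. manA, glcR and ywpJ were read first.

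The alternatives fixed beforehand were the replicate number as a block, the title letter as a covariate, the array as a random block, quantile normalization, leaving out the lowest 25% of genes, a pseudocount of 16, the series matrix spots, a trended and robust variance, a fit of only the groups compared, a minimum log2 change of 1, and leaving out each replicate. Those added after seeing the data were array block with letter covariate (within-array correlation 0.682), the TMM table, leaving out maltose array 1, glucose array 1 or glucose array 2, and median centring without loess.

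The fit was tested on simulated data with the real genes' levels, channel effect and within-array correlation, and 200 of 4173 genes changed in KM283 on mannose. For the strains on mannose it recovered 26% of 50 genes changed by log2 1, 92% at 2 and 100% at 3, with 0 unchanged genes called. The fit with array block and letter covariate recovered 82% at 1 and 100% at 2, 3 and 4, and called 12 unchanged genes. The simulated data were drawn with the array and letter effects that this fit models, which favours it. Figures were drawn with Python and matplotlib.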

Results

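Transcript levels were measured on microarrays in 2 strains of the soil bacterium Bacillus subtilis, named KMO and KM283 in the labels, each grown with glucose, maltose, mannitol or mannose and harvested at an OD600 of 0.25. The labels do not give the genotype of KM283. The series title is about the accumulation of mannose phosphate inside the cell and the release of the glcR-phoC operon from its repressor GlcR. The 16 samples formed 8 groups of 2, and 4173 genes with 1 spot each were tested. The labels speak of replicate cultures without tying a sample to a culture, so p-values measure the spread between these samples, which may be partly technical. Median spot intensity ran from 1440 to 2171 in the 8 samples whose title ends in A and from 123 to 490 in the 8 whose title ends in B. Each strain had 1 A and 1 B sample on every sugar. The number of arrays limits the precision of every value. All changes below are log2 differences of normalized intensities with the standard error (SE) of the limma fit over 8 groups, n = 2 per group, and adjusted p is the Benjamini-Hochberg value of that fit.

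The genes named by the series title were read first, in every sample. manA (BSU12020, positions 1274692 to 1275639 of assembly ASM904v1), which encodes mannose-6-phosphate isomerase, had normalized log2 levels of 9.26 and 9.29 in KMO on glucose and of 14.47 and 15.99 in KMO on mannose. In KM283 the 8 manA levels lay between 8.57 and 10.35, and on mannose they were 10.35 and 10.24. glcR (BSU36300, 3739206 to 3739982), which encodes a repressor of the DeoR family, averaged 7.54 ± 0.25 (SD, n = 2) in KMO on glucose and 9.24 ± 0.93 (SD, n = 2) in KM283 on glucose. Its neighbour ywpJ (BSU36290, 3738343 to 3739200), the gene called phoC in the title, encodes a phosphatase and averaged 7.57 ± 0.06 and 9.04 ± 0.51 (SD, n = 2) in the same groups. The mannose genes manR, manP, manA and yjdF lie next to each other, from BSU12000 to BSU12030. manR encodes the activator of the operon and manP the mannose permease of the phosphotransferase system.

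**Figure D1:**
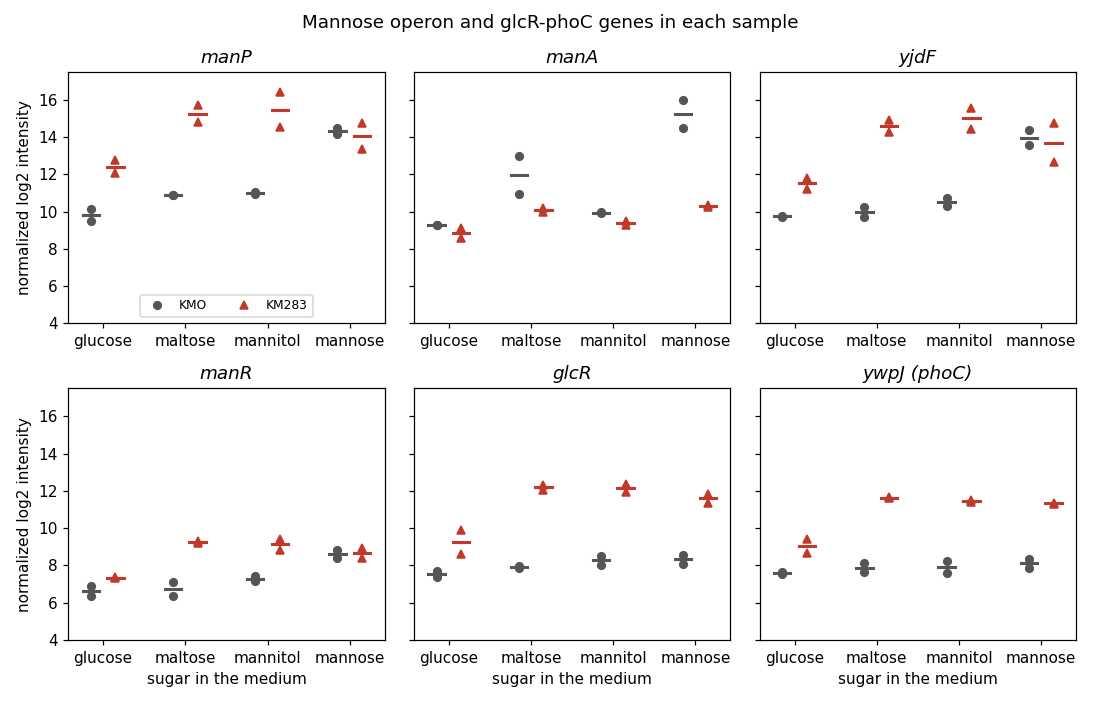
Normalized log2 intensity (y axis) of 6 genes on each sugar (x axis), with a point for each sample and a line for the mean of the 2 samples of a group, circles for KMO and triangles for KM283. On mannose manA lies at 14.47 and 15.99 in KMO and at 10.35 and 10.24 in KM283.

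The comparison of the strains on mannose bears on the title's question most directly. In KM283 glcR was higher by 3.29 ± 0.39 (SE) on the log2 scale (adjusted p = 0.00242), a 9.78-fold difference, and ywpJ by 3.21 ± 0.30 (adjusted p = 0.00112), 9.29-fold. manA was lower, at -4.94 ± 0.57 (adjusted p = 0.00242). Its neighbours manP (-0.27 ± 0.58, adjusted p = 0.998), yjdF (-0.27 ± 0.61) and manR (0.04 ± 0.31) did not pass the test, and neither did the other isomerase genes pmiA (0.07 ± 0.23) and gmuF (0.35 ± 0.49). liaI, of the cell envelope stress operon, was higher by 2.17 ± 0.24, and rocA and rocE, of arginine catabolism, by 2.04 ± 0.25 and 1.62 ± 0.26. Among the lower genes were ptsG, the glucose permease (-2.81 ± 0.40, adjusted p = 0.00774), and lctE, lactate dehydrogenase (-4.06 ± 0.68, adjusted p = 0.0206). The lctE difference was not confined to mannose, at -3.39 ± 0.68 on mannitol (adjusted p = 0.0431) and -2.84 ± 0.68 on maltose (adjusted p = 0.214). The others named by the rule were pdhB (-1.82), pyrG (-1.67), prs (-1.54), yomX (-1.77), yomV (-1.58) and yjlC (-1.58), and the calls of pdhB, prs and pyrG were lost in 12, 11 and 10 of 18 alternative settings, quantile normalization among them.

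Gene lists fixed beforehand were then counted on mannose. The pyrimidine genes from pyrR to pyrE lie next to each other (BSU15470 to BSU15560). So do the glycolysis genes from eno to cggR (BSU33900 to BSU33950). Such members are not independent, so counts of these lists, here and below, may count a shared change several times. The camera value with the preset correlation may then overstate the evidence. Of 10 glycolysis genes 3 fell, gapA (-2.45 ± 0.28), pgk (-1.51 ± 0.20) and cggR (-1.23 ± 0.24), and 8 fell when adjusted over the list alone (camera adjusted p = 5.97e-16, and adjusted p = 0.00589 with an estimated correlation). Of 11 pyrimidine biosynthesis genes 3 fell, pyrAB (-4.73 ± 0.71), pyrK (-4.54 ± 0.59) and pyrG (-1.67 ± 0.30, lost in 10 of 18 settings), and 10 fell when adjusted over the list alone (camera adjusted p = 3.3e-21, and adjusted p = 0.0212 with an estimated correlation). Of 18 genes of overflow metabolism and fermentation 2 fell, lctE and pdhB (lost in 12 of 18 settings), and 9 when adjusted over the list alone (adjusted p = 0.0104 with an estimated correlation). No member of the 15 fatty acid synthesis genes passed over all genes, and 4 fell when adjusted over the list alone, with plsC at -1.33 ± 0.44 and fapR at -1.33 ± 0.33 (adjusted p = 0.0219 with an estimated correlation). Of 9 glucose uptake genes only ptsG fell over all genes, and 2 fell when adjusted over the list alone (adjusted p = 0.0345 with an estimated correlation). Of 4 mannose utilisation genes only manA fell (adjusted p = 0.292 with an estimated correlation).

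limma called 21 of 4173 genes on mannose, 5 higher and 16 lower in KM283, while median centring in place of loess gave 5 and 7. The excess of lower calls was not seen without KM283 replicate 2 or without KM283 replicate 3. With the array as a block and the title letter as a covariate, a fit chosen after seeing the data, 331 genes were called. Of these 58 were higher and 273 lower, and the 21 were among them. The fit over 8 groups leaves out both the presumed pairing on arrays and the title letter, so its SE of a strain difference was wider. For glcR on mannose it was 0.389, against 0.214 with array block and letter covariate. On the 2 arrays taken singly the KM283 over KMO ratio was 3.30 and 3.28 for glcR, 3.02 and 3.41 for ywpJ and -4.13 and -5.75 for manA (log2). Leaving out KMO replicate 4 gave 7 calls and ended those of ptsG, rocA and lctE, among others.

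On maltose the operon genes and the mannose genes were higher in KM283. glcR rose by 4.28 ± 0.39 (adjusted p = 0.00027), ywpJ by 3.76 ± 0.30 (adjusted p = 0.000107), yjdF by 4.61 ± 0.61, manP by 4.36 ± 0.58 and manR by 2.52 ± 0.31, whereas manA was at -1.89 ± 0.57 (adjusted p = 0.527, and 0.00903 with array block and letter covariate). chrA was higher by 3.27 ± 0.47. malA, which encodes a phospho-glucosidase needed for growth on maltose, was lower at -4.65 ± 0.30 (adjusted p = 2.18e-05), and malR, its regulator, was at -1.67 ± 0.22 (adjusted p = 0.00362). malP, which lies next to malR, had a mean level of 11.3 in both strains. mdxF and mdxG were not lower in KM283, with mean levels of 9.88 against 9.3 and 8.74 against 8.07 in KMO. ptsG (-3.29 ± 0.40) and yomX (-1.86 ± 0.30) were lower as well. Of 4 mannitol genes mtlD (-3.27 ± 0.41) and mtlF (-2.83 ± 0.46) fell, and 3 fell when adjusted over the list alone (adjusted p = 0.00509 with an estimated correlation). Of 4 mannose utilisation genes 3 rose (adjusted p = 0.0207 with an estimated correlation).

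The maltose comparison had 17 calls, 9 higher and 8 lower in KM283, against 9 and 14 on the quantile-normalized series matrix spots, which lack KMO maltose replicate 1, and 9 and 15 without that replicate alone. The fit with array block and letter covariate called 161, 89 higher and 72 lower, the 17 among them. Leaving out KM283 replicate 2 gave 8 calls and ended those of manP and yjdF, while leaving out KM283 replicate 3 gave 40. Without the 2 samples of maltose array 1, which had the lowest correlations with the other samples, 14 were called, and manP, manR and yjdF were not among them.

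On mannitol the same 5 genes were higher in KM283. yjdF rose by 4.49 ± 0.61, manP by 4.46 ± 0.58, glcR by 3.89 ± 0.39 (adjusted p = 0.000543), ywpJ by 3.55 ± 0.30 (adjusted p = 0.000197) and manR by 1.83 ± 0.31 (adjusted p = 0.0187), and manA was at -0.57 ± 0.57 (adjusted p = 0.952). rbsD and rbsR, of the ribose operon, rose by 3.48 ± 0.65 and 3.02 ± 0.60. Of 4 mannitol utilisation genes 3 fell, mtlD (-4.99 ± 0.41), mtlF (-4.79 ± 0.46) and mtlA (-4.14 ± 0.50), as did 3 when adjusted over the list alone (adjusted p = 0.00387 with an estimated correlation). mtlD encodes mannitol phosphate dehydrogenase, and mtlA and mtlF the mannitol permease. Of 11 pyrimidine genes 5 fell, with pyrK at -4.84 ± 0.59, pyrAB at -4.83 ± 0.71 and pyrE at -4.29 ± 0.76, and 10 fell when adjusted over the list alone (adjusted p = 0.0283 with an estimated correlation). Of 10 glycolysis genes 3 fell, gapA (-2.26 ± 0.28), cggR (-1.59 ± 0.24) and pgk (-1.09 ± 0.20), and 5 when adjusted over the list alone (adjusted p = 0.0258 with an estimated correlation).

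The mannitol comparison had 38 calls, 16 higher and 22 lower in KM283. The fit with array block and letter covariate called 575, 204 higher and 371 lower, the 38 among them. Leaving out KMO replicate 4 gave 7 calls and ended those of manP and yjdF, and 12, 21 and 16 were called without KMO replicate 1, KM283 replicate 2 and KM283 replicate 3.

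On glucose limma called 0 genes between the strains, with 133 at an unadjusted p under 0.05. glcR was at 1.71 ± 0.39 (adjusted p = 0.55), ywpJ at 1.46 ± 0.30 (adjusted p = 0.473) and manP at 2.58 ± 0.58 (adjusted p = 0.55). On the 2 arrays the ratio was 2.19 and 1.23 for glcR, 1.78 and 1.15 for ywpJ and 2.60 and 2.55 for manP. manA was at -0.42 ± 0.57 and yjdF at 1.77 ± 0.61. Of the 2 operon genes both were higher when adjusted over the list alone (camera adjusted p = 2.5e-08, and adjusted p = 0.0645 with an estimated correlation).

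With array block and letter covariate 49 genes were called on glucose, 12 higher and 37 lower in KM283, among them glcR (adjusted p = 0.00552), ywpJ (adjusted p = 0.00912), manP (adjusted p = 0.0211) and yjdF (adjusted p = 0.0388). Across all genes the log ratios of the 2 glucose arrays correlated at -0.111, against 0.339, 0.623 and 0.416 for maltose, mannitol and mannose. Leaving out KM283 replicate 3 gave 15 calls and leaving out KMO replicate 1 gave 7.

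Each sugar was then set against glucose within KMO. On mannose manA rose by 5.95 ± 0.57 (adjusted p = 0.0015), manP by 4.50 ± 0.58 (adjusted p = 0.0153), yjdF by 4.23 ± 0.61 (adjusted p = 0.0257) and manR by 1.98 ± 0.31 (adjusted p = 0.0483), so that 4 of 4 mannose utilisation genes rose (adjusted p = 0.0143 with an estimated correlation). glcR (0.77 ± 0.39) and ywpJ (0.54 ± 0.30) did not pass. These 4 genes were the only calls. With array block and letter covariate manA alone was called, the manR call was lost in 12 of 18 settings, and leaving out KMO glucose replicate 4 gave 1 call, KMO glucose replicate 1 25, KMO mannose replicate 1 15 and KMO mannose replicate 4 1.

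On mannitol KMO had 4 calls, all higher than on glucose. mtlF rose by 7.46 ± 0.46 (adjusted p = 8.7e-06), mtlD by 6.38 ± 0.41, mtlA by 5.71 ± 0.50 and treA, a phospho-trehalase gene, by 2.52 ± 0.39 (adjusted p = 0.0392). Of 4 mannitol utilisation genes 3 rose (adjusted p = 0.000145 with an estimated correlation). glcR was at 0.73 ± 0.39 and manA at 0.67 ± 0.57, and neither passed. The fit with array block and letter covariate called 3 genes, without treA, whose call was lost in 9 of 18 settings, and leaving out KMO glucose replicate 1 gave 18 calls.

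On maltose KMO had 148 calls, 58 higher and 90 lower than on glucose. malA rose by 6.13 ± 0.30 (adjusted p = 1.02e-06), treA by 5.73 ± 0.39, mtlF by 4.47 ± 0.46, treP, the trehalose permease, by 3.99 ± 0.35 and xylA, xylose isomerase, by 3.87 ± 0.36. manA was at 2.71 ± 0.57 (adjusted p = 0.0292), with levels of 10.96 and 13.01 in the 2 maltose samples. Without KMO maltose replicate 4 that change was 1.684, without KMO maltose replicate 1 it was 3.735, and the call was lost in 7 of 18 settings. manP (1.07 ± 0.58) and glcR (0.38 ± 0.39) did not pass. Of 11 maltose genes 5 rose, among them malR (3.43 ± 0.22), mdxF (2.05 ± 0.38) and mdxG (1.96 ± 0.35), and 7 when adjusted over the list alone (adjusted p = 0.148 with an estimated correlation). malP hardly moved, from a mean level of 11.12 on glucose to 11.3 on maltose. Of 11 pyrimidine genes 5 fell, with pyrK at -4.89 ± 0.59, pyrF at -3.59 ± 0.75, pyrAB at -3.38 ± 0.71 and pyrE at -3.25 ± 0.76 (adjusted p = 0.148 with an estimated correlation). alsS, acetolactate synthase, was at -3.60 ± 0.67. The maltose array with title number 1 had the lowest correlations with the other samples, and without its 2 samples 47 genes were called, 37 higher and 10 lower. The series matrix spots, quantile-normalized and without KMO maltose replicate 1, gave 20 higher and 7 lower, and leaving out that replicate alone gave 20 and 9. Leaving out KMO glucose replicate 4 gave 12 calls and KMO maltose replicate 4 51. With array block and letter covariate pyrAB (adjusted p = 0.058) and pyrE (adjusted p = 0.052, lost in 10 of 18 settings) were not called.

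Within KM283 the operon genes rose on each of the other sugars. On mannose glcR rose by 2.36 ± 0.39 (adjusted p = 0.0256), ywpJ by 2.29 ± 0.30 (adjusted p = 0.00982) and liaI by 2.20 ± 0.24 (adjusted p = 0.00351), and fecF rose by 1.31 ± 0.22. manA was at 1.44 ± 0.57 (adjusted p = 0.223), manP at 1.65 ± 0.58 (adjusted p = 0.179), yjdF at 2.19 ± 0.61 (adjusted p = 0.0962) and manR at 1.34 ± 0.31 (adjusted p = 0.073). Lower were pyrK (-4.29 ± 0.59), lctE (-4.05 ± 0.68), ptsG (-2.69 ± 0.40), gapA (-2.07 ± 0.28) and sufU, of iron-sulfur cluster assembly (-2.06 ± 0.23). Of 10 glycolysis genes 2 fell, and 6 when adjusted over the list alone (adjusted p = 0.135 with an estimated correlation). There were 19 calls, 4 higher and 15 lower, against 10 and 14 on the quantile-normalized series matrix spots. Array block with letter covariate gave 37. Leaving out KM283 glucose replicate 2 raised the number of calls and leaving out KM283 mannose replicate 3 lowered it. Without KM283 mannose replicate 3 glcR, ywpJ and pyrK were not called, nor were others of the lower genes named here. Without KM283 mannose replicate 2 the higher calls outnumbered the lower ones. The fecF call was lost in 8 of 18 settings.

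On maltose KM283 had 47 calls, 35 higher and 12 lower than on glucose. glcR rose by 2.95 ± 0.39 (adjusted p = 0.00396), ywpJ by 2.61 ± 0.30, yjdF by 3.08 ± 0.61, manP by 2.85 ± 0.58 and manR by 1.93 ± 0.31. rbsD (4.15 ± 0.65), rbsA (3.92 ± 0.80), rbsR (3.50 ± 0.60), treA (4.05 ± 0.39) and treP (3.54 ± 0.35) rose. Of 11 maltose genes 5 rose, among them mdxF (2.75 ± 0.38), mdxG (2.68 ± 0.35) and malR (1.91 ± 0.22), and 8 when adjusted over the list alone (adjusted p = 0.0676 with an estimated correlation). pyrK (-5.06 ± 0.59), pyrF (-3.94 ± 0.75), pyrAB (-3.74 ± 0.71), ptsG (-2.11 ± 0.40) and yhbI (-1.97 ± 0.39) were lower. Leaving out KM283 maltose replicate 2 gave 15 calls, leaving out KM283 glucose replicate 3 gave 27, and array block with letter covariate gave 43. That fit did not call manP (adjusted p = 0.116), manR (adjusted p = 0.0705) or pyrAB (adjusted p = 0.0728). Of 18 alternative settings the calls of manP and rbsA were lost in 11, those of yjdF and yhbI in 9 and that of ptsG in 8.

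On mannitol KM283 had 22 calls, 16 higher and 6 lower. glcR rose by 2.92 ± 0.39 (adjusted p = 0.00991), ywpJ by 2.43 ± 0.30 (adjusted p = 0.00905), yjdF by 3.50 ± 0.61, manP by 3.06 ± 0.58 and manR by 1.80 ± 0.31, and manA was at 0.52 ± 0.57 (adjusted p = 0.97). mtlF rose by 3.12 ± 0.46 and was the only called member of 4 mannitol genes, with 3 when adjusted over the list alone (adjusted p = 0.0296 with an estimated correlation). rbsD (3.93 ± 0.65) and rbsR (3.34 ± 0.60) were higher. pyrK (-3.67 ± 0.59), ptsG (-2.44 ± 0.40), gapA (-2.21 ± 0.28), cggR (-1.47 ± 0.24) and sufU (-1.38 ± 0.23) were lower. Leaving out KM283 mannitol replicate 2 left 0 calls and KM283 mannitol replicate 3 left 3, and array block with letter covariate gave 15. That fit called neither manP (adjusted p = 0.121), manR (adjusted p = 0.121), mtlF (adjusted p = 0.0572), pyrK (adjusted p = 0.0895) nor gapA (adjusted p = 0.0553). Of 18 alternative settings the manP call was lost in 13, that of manR in 11, that of rbsR in 10 and those of yjdF, ptsG, cggR and sufU in 8.

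**Figure D2:**
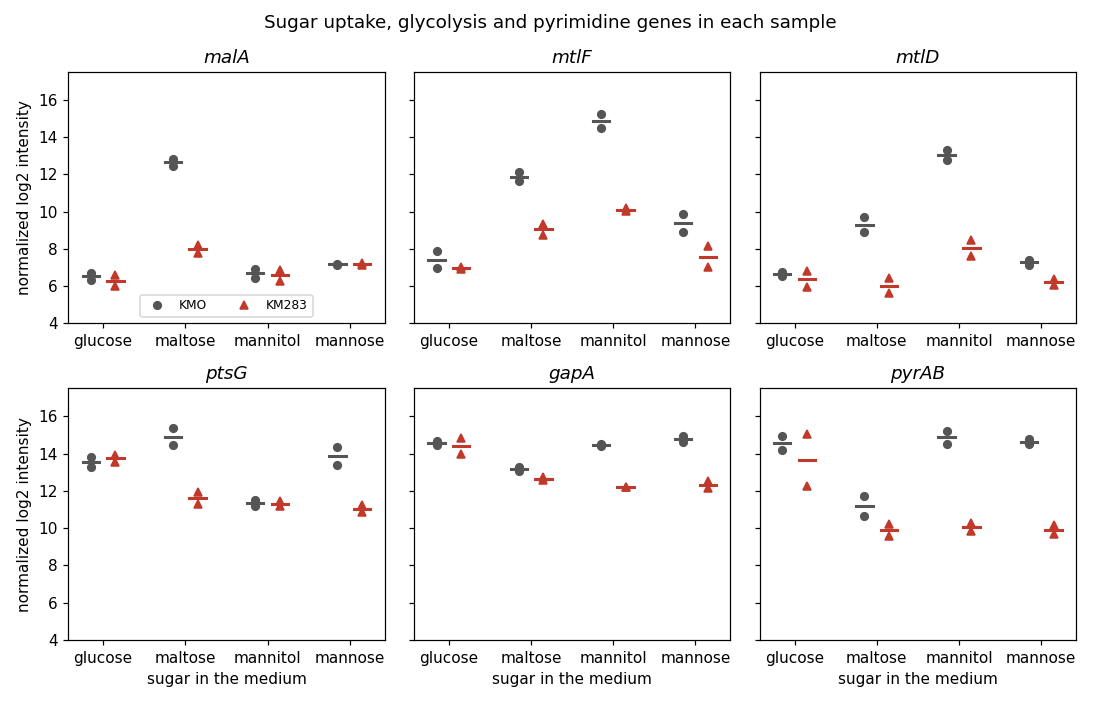
Normalized log2 intensity (y axis) of 6 genes on each sugar (x axis), with a point for each sample and a line for the mean of the 2 samples of a group, circles for KMO and triangles for KM283. On maltose malA differs between the strains by -4.65 and on mannitol mtlD by -4.99 (log2, KM283 over KMO).

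Whether the strain difference itself depended on the sugar was tested as the difference from that on glucose. On maltose malA was the single call, at -4.42 ± 0.43 (adjusted p = 0.00154), and on mannitol mtlD was, at -4.71 ± 0.57 (adjusted p = 0.0166). On mannose limma called 0 genes, with 68 at an unadjusted p under 0.05. There manA was at -4.52 ± 0.81 (adjusted p = 0.287), glcR at 1.58 ± 0.55 and ywpJ at 1.75 ± 0.43. Of 4 mannose utilisation genes 3 were lower when adjusted over the list alone (adjusted p = 0.00691 with an estimated correlation), and both operon genes were higher (adjusted p = 0.0219 with an estimated correlation). On mannose itself manP was at a level of 14.06 in KM283 and 14.33 in KMO, and yjdF at 13.7 and 13.97. Their terms mainly reflect glucose, where manP was at 12.41 and 9.83 and yjdF at 11.51 and 9.74. On maltose glcR was at 2.57 ± 0.55 (adjusted p = 0.316), and on mannitol at 2.19 ± 0.55 (adjusted p = 0.762). The fit with array block and letter covariate called 54 genes on maltose, 76 on mannitol and 30 on mannose, with manA among the last (adjusted p = 0.00292). It called glcR on all 3 sugars (adjusted p = 0.00499, 0.00623 and 0.0445) and ywpJ likewise (adjusted p = 0.00559, 0.00613 and 0.0223), so whether these differences depend on the sugar rests on the fit chosen. It called yjdF on maltose and mannitol (adjusted p = 0.0263 and 0.0254) and manR on maltose (adjusted p = 0.0309). Without KMO glucose replicate 1, KMO glucose replicate 4, KMO mannitol replicate 1 or KMO mannitol replicate 4 the mtlD call was lost. A fit of only the groups compared called neither malA nor mtlD.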

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

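The tests of explanations in this part were chosen after the result was seen. The strain difference was unlike that on glucose for malA, at -4.42 ± 0.43 on maltose, and for mtlD, at -4.71 ± 0.57 on mannitol (limma interaction terms, n = 2 per group). On glucose both genes were low in both strains, malA at 6.52 in KMO and 6.30 in KM283 and mtlD at 6.66 and 6.37. A lower level in KM283 could hardly show there, so these terms mainly restate the difference on maltose and mannitol. mtlD was also lower in KM283 on maltose (-3.27 ± 0.41). A fit of only the groups compared called neither term.

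Both genes, with mtlA and mtlF, were lower in KM283 on the sugar they serve. A channel bias would turn the sign between the 2 arrays of a sugar, on which the strains exchange channels, and the ratio nearest to 0 among malA on maltose and mtlA, mtlF and mtlD on mannitol was -3.58, with -2.01 and -1.14 for mtlR, which was called with array block and letter covariate but not in the fit over 8 groups, so that explanation is argued against. Sugar labels exchanged among the KM283 samples would put malA or mtlD highest under another sugar, but both were highest under their own, by at least 0.57 for malA and 0.85 for mtlD (log2). What stays open is the strain itself, whose genotype is not in the labels, and exchange with a sample outside the series, neither of which was tested.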

How the results depend on the processing

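Counts of called genes are given in this order: KM283 over KMO on glucose, maltose, mannitol and mannose, then maltose, mannitol and mannose over glucose in KMO and the same 3 in KM283, then the differences of strain differences on maltose, mannitol and mannose. The reported counts were 0, 17, 38, 21, 148, 4, 4, 47, 22, 19, 1, 1 and 0. Of the alternatives planned before the data were examined, a minimum log2 change of 1 (0, 17, 37, 21, 141, 4, 4, 46, 22, 19, 1, 1 and 0) and a trended and robust variance (0, 17, 30, 19, 135, 4, 4, 46, 20, 16, 1, 1 and 0) moved no count by over 1.5 times. Quantile normalization gave 0, 17, 38, 16, 137, 5, 3, 46, 23, 26, 2, 2 and 1, a pseudocount of 16 0, 17, 36, 24, 154, 4, 3, 47, 21, 36, 1, 2 and 0, leaving out the lowest 25% of genes 0, 14, 35, 19, 138, 4, 4, 49, 24, 41, 0, 2 and 0 and the series matrix spots, quantile-normalized and without KMO maltose replicate 1, 0, 23, 25, 15, 27, 5, 4, 35, 18, 24, 4, 2 and 2. The title letter as covariate gave 1, 18, 67, 35, 170, 3, 2, 61, 23, 49, 1, 2 and 0, the array as a random block 6, 42, 189, 107, 100, 4, 4, 43, 13, 16, 8, 11 and 4, and a fit of only the groups compared 0, 6, 136, 8, 34, 3, 5, 0, 5, 0, 0, 0 and 0, which has fewer residual degrees of freedom. With the replicate block, the counts were 0, 19, 81, 41, 172, 3, 1, 67, 24, 89, 2, 1 and 0. Whether the replicate numbers pair the samples stayed unsettled. Within a strain each replicate number held the same title letter on every sugar. A difference between replicates is therefore also a difference between letters, and its correlation across sugars cannot tell pairing from a channel effect. These correlations ran from -0.126 to 0.161 in KMO, with 3 of 6 pairs of sugars above 0.1. In KM283 they ran from 0.0817 to 0.285, with 5 of 6 above 0.1. The samples were not taken as pairs, because not every correlation lay above 0.1. The replicate block thus acts as a letter covariate within each strain. It ended 9 of 97 calls of named genes, among them manP and yjdF in KM283 on maltose and on mannitol over glucose. Of the alternatives chosen after seeing the data, array block with letter covariate gave 49, 161, 575, 331, 121, 3, 1, 43, 15, 37, 54, 76 and 30, median centring without loess 0, 18, 38, 12, 94, 4, 2, 36, 12, 4, 1, 1 and 0, and the TMM table, whose locus tags are in doubt, 0, 3, 0, 0, 6, 0, 1, 0, 0, 1, 0, 0 and 0. Leaving out maltose array 1 gave 0, 14, 30, 17, 47, 3, 8, 28, 18, 43, 3, 2 and 0, glucose array 1 7, 19, 63, 27, 241, 61, 82, 94, 71, 127, 3, 12 and 0 and glucose array 2 5, 19, 63, 27, 32, 4, 4, 28, 27, 31, 4, 6 and 1. Leaving out 1 replicate of the compared groups at a time gave, in the same order, 0 to 15, 8 to 40, 7 to 21, 7 to 16, 12 to 119, 3 to 18, 1 to 25, 15 to 67, 0 to 21, 5 to 63, 1 to 6, 0 to 7, 0 to 4, where the lone sample left is assumed to vary like the other groups. Leaving out an array or a replicate left a single title letter in the affected group, as did the series matrix spots for KMO on maltose. A dye effect then no longer cancels in comparisons with that group, and it may contribute to these counts. Apart from these constructions, the cause was not tested. Of 97 calls of named genes, 91 held with quantile normalization, 83 with array block and letter covariate, 88 with the replicate block, 66 without maltose array 1 and 39 with only the groups compared, and none changed sign. The calls of glcR and ywpJ between the strains on maltose, mannitol and mannose held in every setting run on the spot values. Of 180 camera calls of lists, 31 held with an estimated correlation. Signal over background could not be assessed, since the tables hold no background values, and B samples have the lower signal.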

Other observations

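The strain comparisons hold further genes not described above, given here as single genes with no set test. The ribose operon genes rbsD, rbsR, rbsA, rbsC, rbsB and rbsK were at 3.48, 3.02, 3.00, 2.06, 2.77 and 2.02 (log2, KM283 over KMO) on mannitol, of which limma called rbsD (adjusted p = 0.0344) and rbsR (adjusted p = 0.0431). On mannose the same 6 genes were at 2.25, 2.14, 1.87, 1.17, 1.52 and 1.24, with 0 called. rbsD was at 1.98 on maltose and 1.37 on glucose and was called on neither. Its adjusted p with array block and letter covariate was 0.00853 on maltose and 0.0731 on glucose. Array block with letter covariate, chosen after seeing the data, called all 6 on mannitol and all but rbsB (adjusted p = 0.0635) on mannose. liaI was higher in KM283 on maltose (1.74 ± 0.24, adjusted p = 0.00443), mannitol (1.26 ± 0.24, adjusted p = 0.0359) and mannose (2.17 ± 0.24), and at 0.42 ± 0.24 on glucose (adjusted p = 1). liaH, of the same operon, did not pass on any of the 4 sugars (0.39 ± 0.23 on maltose, 0.14 ± 0.23 on mannitol and 0.90 ± 0.23 on mannose), though it did on mannose with array block and letter covariate (adjusted p = 0.00412). rocA and rocE were higher on maltose (1.87 ± 0.25 and 2.00 ± 0.26) and mannitol (2.43 ± 0.25 and 1.98 ± 0.26). rocD, rocB and rocC, also of arginine catabolism, did not pass there, at 0.46, 0.51 and 0.25 on maltose and 0.79, 0.77 and 0.50 on mannitol, where array block with letter covariate called rocD (adjusted p = 0.00711) and rocB (adjusted p = 0.00431). These genes were chosen after their values were seen, apart from those named by the rule.

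With array block and letter covariate, 15 genes were called in the same direction between the strains on all 4 sugars. glcR, ywpJ, rocA and rocE were higher in KM283. The other 11 were lower, among them yomX (-1.94, -1.86, -1.77 and -1.77 on glucose, maltose, mannitol and mannose) and yomV (-1.54, -1.66, -1.57 and -1.58), with yorI, yonF, yonE, yonC, yomR, yomN, yomG and yomF of the same chromosomal neighbourhood, which belongs to the SP-beta prophage, and fbpB. The yomX and yomV spots were weak. Their highest intensities in any sample were 1384 and 1301, against a lowest sample median of 1440 among A samples. Along the chromosome, the mean strain ratio over windows of 15 loci exceeded the highest of 1000 shuffled orders (0.745) in 1 window, from pyrR to sumT, at -1.56 as the mean over 8 arrays, of which 7 shared the sign. By sugar that mean was -0.57 on glucose, -0.69 on maltose, -2.59 on mannitol and -2.40 on mannose. The shuffles separated neighbouring genes, whose profiles correlate, so a changed run of such genes could exceed them. The window holds the pyrimidine genes described above and adds no separate support to them.

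The tests of the next patterns were chosen after the result was seen. manR, manP, yjdF, glcR and ywpJ were higher in KM283 on maltose and mannitol, without mannose as the named sugar. A channel bias would turn the sign on 1 of the arrays, but the lowest of the 20 log2 ratios was 1.67. RNA of KMO mannose cultures in these samples would bring manA with manP, but the highest manA level lay at -4.29 relative to the lowest of KMO on mannose. Mannose in the medium of both strains would also raise the mannose genes in KMO. In KMO on mannitol over glucose, manP was at 1.17 ± 0.58, yjdF at 0.78 ± 0.61 and manA at 0.67 ± 0.57. On mannose over glucose they were at 4.5, 4.23 and 5.95. For these genes, the values argue against mannose in the mannitol medium at a level that induces KMO. On maltose manP was at a level of 10.9 in KMO, against 14.33 on mannose and 9.83 on glucose. yjdF was at 9.99 on maltose, against 9.74 on glucose and 13.97 on mannose. manR was at 6.73, against 6.64 and 8.62. These 2 genes lay near their glucose levels, but manA rose by 2.71 over glucose, with 10.96 and 13.01 in the 2 samples. The genes thus point different ways on maltose. Mannose in the maltose medium and the strain stay open, and neither was tested.

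The TMM table did not match the spot table by locus. Locus tags in another order are a candidate explanation, since the profiles of neighbouring loci correlated at -0.000797, as in shuffled orders. Combining probes and TMM scaling would keep the order of levels, but the highest Spearman correlation by locus was 0.00786. No biological explanation was tested for this pattern.

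manA lay between percentiles 38.4 and 69.2 of all genes in the 8 KM283 samples, and at 98.6 and 100 in the 2 KMO samples on mannose. In KMO it lay at 50.1 and 51.3 on glucose and at 61.9 and 62.2 on mannitol, within the range of KM283. On maltose it lay at 78 and 96.1 in KMO.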
